A study of Mus musculus with 4 samples.

How the data were processed

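The data were 4 chromatin immunoprecipitation sequencing libraries from male C57BL/6 mouse liver, namely an H3K23pr immunoprecipitate (IP) and an input for each of 2 genotypes. The genotypes were the RPN11 flox/flox control, called WT here after the sample titles, and the hepatocyte-specific RPN11 knockout, called KO. Each group held 1 library. Groups were taken from the titles and genotype labels.

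Per the labels' protocols, liver chromatin was crosslinked with formaldehyde, sonicated and precipitated with an antibody against propionylated lysine 23 of histone H3. Per the submitters' processing notes, reads were trimmed with cutadapt 1.9.3 and aligned with Bowtie2 2.2.4 to mm10. Per the file headers, MACS2 2.1.1.20160309 called narrow peaks in paired-end mode, each IP against its own input. The headers gave a p cutoff of 0.001, an effective genome size of 1870000000 bp and at most 2 fragments with the same ends. The alignment names in the headers carry a mark of duplicate removal, but the caller still dropped fragments with the same ends, so how far duplicates had been removed before is not known. IP fragments went from 15588633 to 13615838 in WT and from 17764217 to 15468265 in KO. A summit of 4 fragments can therefore hold as few as 2 different fragments. The peak lists were called per library and not on pooled samples.

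The pileup deposited by the authors was read as a signal, the whole number of IP fragments over the peak summit. The fold in the deposited lists is the ratio of the pileup to the local background, with a pseudocount of 1 added to both. The deposited p and q values are given as −log10 values per peak. The headers said that q would not be calculated, but the q column held values. It was used only in alternatives and to describe peaks. Peak length and summit position, both deposited by the authors, were in bp. The fold, p and q of each peak are the authors' own, and were used to describe, rank and filter peaks within a list. Recomputing p as a Poisson tail from the pileup and the background implied by the fold matched the deposited value within 0.01 on the −log10 scale for 99.9945% of WT peaks and 99.9976% of KO peaks. This background was used below as the authors' value for a site. Its lowest common level, the genome-wide background, was 0.692 fragments in WT and 0.568 in KO.

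Per the file headers, the WT libraries held 13615838 IP and 9385834 input fragments after duplicate filtering, and the KO libraries held 15468265 and 10000823. Mean fragment size was 97 bp in the WT IP and 71 bp in the KO IP. Exact (Clopper-Pearson) 95% binomial intervals are given for shares and for ratios of fragment counts, and they cover counting error only. No p-value across genes was computed.

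Gene positions came from a RefSeq table of GRCm38.p6, the assembly of mm10, with 21887 protein-coding genes on assembled chromosomes. The table gives the start and end of each gene but no strand or exons, so transcription start sites were not located. The plan named a promoter as 2 kb around the start site. In its place a gene counted as marked when a peak overlapped the 2 kb on either side of either gene end. Where the plan took the gene body with 2 kb upstream, 2 kb on both sides was used. Peaks were placed by their midpoint within 2 kb of a gene end, inside a gene but further from its ends, or outside genes. Distances to a gene end are from the peak midpoint.

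Peaks of the 2 lists were called shared when they overlapped by at least 1 bp. The expected overlap came from 100 random placements, in which each peak was put anywhere on its chromosome after the first 3 Mb or, as a choice made after seeing the data, moved by 20 to 100 kb. The 23 gene lists and the rule for naming genes were fixed before the data were examined. Of the 569 distinct symbols in the lists, 567 matched, and the other 2, Mut and G6pc1, were synonyms of the members Mmut and G6pc. The lists covered 5 lipid pathways, other liver metabolism, histone acylation, the proteasome, m6A, hepatocyte identity, stress, inflammation, cell cycle, markers of other liver cells and comparison genes. For each list the number of marked members was set among 10000 random lists of protein-coding genes. The number of WT-marked members without a KO peak was set among 10000 random lists of WT-marked genes, matched on the decile of peak rank, and likewise with the genotypes exchanged. A list stood apart when its count fell outside the central 95% of the random lists. Counts are whole numbers, so fewer than 5% of random lists fall outside, and the number of lists expected outside was summed from the random lists. The percentiles describe these libraries and are not tests of genotype.

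The named genes were the 10 strongest by caller p among WT-only and among KO-only genes and the 10 with the smallest rank sum among genes marked in both, without predicted genes (Gm and Rik symbols). Psmd14, Mettl3 and Acss3 were added, and for each list up to 4 WT-only, 4 shared and 2 KO-only genes. Genes outside this rule are said to have been chosen after their values were seen. Alternatives covered peak thresholds, lists of equal length, overlap rules, gene windows and matching. Those on q, on fragment minima above the called peaks, on background, and on windows for coverage and gain were chosen after seeing the data.

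Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and bedtools 2.31.1 served as a check. In a simulated KO list of 41907 peaks with 8381 planted on WT peaks, all 8381 were found, and the 8566 overlapping peaks in all equalled the number from bedtools. In simulated losses over 3315 marked genes, 0.5% of unchanged lists and 100% of planted lists of 25 genes stood apart. The real lists held at most 6 marked genes in WT and 8 in KO, too few for a complete loss or gain to be called, so the planted lists do not bear on them. For the closing section, the chance overlap of weak peaks was tried with moves over 5 ranges of distance, and the range with the highest expectation was kept. Fragments were also placed at random in a simulation, which was set aside because its number of chance peaks depended on the genome size assumed. No sequence, exon or strand information was used.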

Results

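H3K23pr, the propionylation of lysine 23 on histone H3, was mapped by ChIP-seq in mouse liver with and without RPN11. RPN11, encoded by Psmd14, is the deubiquitylating subunit of the 26S proteasome lid, and the series concerns fatty liver disease. The WT library came from flox/flox liver and the KO library from liver with a hepatocyte-specific RPN11 knockout, with 1 IP and 1 input per genotype. After duplicate filtering the IP libraries held 13615838 fragments in WT and 15468265 in KO. All differences below are between these libraries and have no replicate check.

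The targeted gene was considered first. Psmd14 (chromosome 2, 61711694 to 61800376, mm10) carried 7 peaks in WT and 10 in KO within the gene and 2 kb around it. All were low, with 4 to 6 IP fragments at the summit in WT and 4 to 7 in KO. The genotypes shared 1 site, at 61715585 to 61715699 in WT and 61715557 to 61715634 in KO, with 6 fragments in both. Among the 648 protein-coding genes within 10% of its length, the peak number of Psmd14 was at percentile 98.1 in WT and 99.8 in KO, where the medians were 2 and 1. With peaks of at least 5 fragments it was at percentile 92.0 in WT, with 4 peaks, and 99.5 in KO, with 7. Peaks do not check the knockout, because the position of the floxed part was not used here and DNA of cells other than hepatocytes remains.

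Acss3, which encodes an acyl-CoA synthetase that activates propionate, had 8 peaks in WT and 15 in KO. The gene lies on chromosome 10 from 106933514 to 107123761. No WT peak overlapped a KO peak there. In KO, 3 peaks fell within 2 kb of the lower-coordinate end, and the strongest of these, at 106934726 to 106934880, had 8 fragments and a fold of 5.08. WT had no peak within 2 kb of either end. Against 286 genes of like length, the KO number was at percentile 99.3 and the WT number at 87.8. With at least 5 fragments, KO had 6 peaks (percentile 91.8) and WT 5 (83.7). Mettl3, the catalytic subunit of the m6A RNA methyltransferase, had 1 WT peak of 5 fragments at its end (chromosome 14, 52294808 to 52294955) and no KO peak. Among 1077 genes of like length the median was 0 peaks in both lists, and Mettl3 was at percentile 82.8 in WT and 41.8 in KO.

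**Figure D1:**
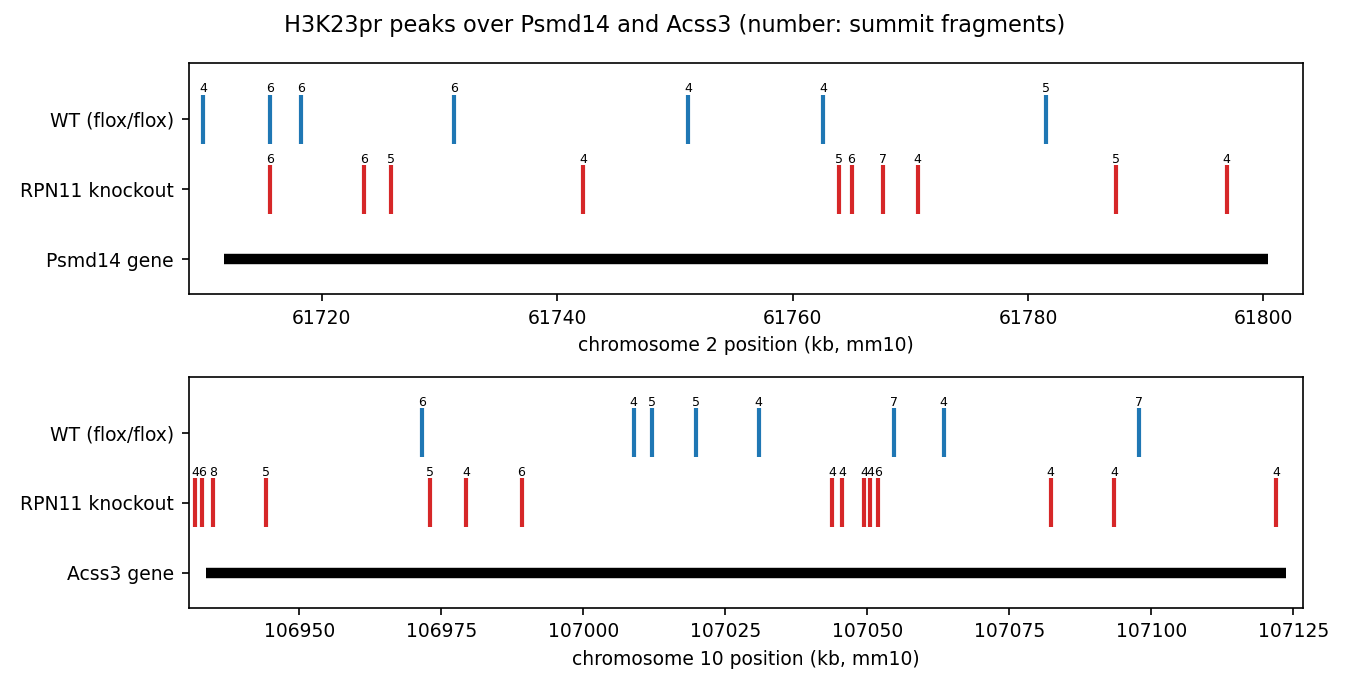
Peaks over Psmd14 and Acss3 by position on chromosomes 2 and 10 (kb, mm10), with WT peaks in blue, KO peaks in red, the gene as a black bar and the summit fragments written above each peak. The 10 KO peaks of Psmd14 and the 15 of Acss3 are low, at most 8 fragments high, and 1 pair, near the lower-coordinate end of Psmd14, overlaps.

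The next comparison asked which genes had a called H3K23pr peak near an end in either genotype, with lipid metabolism as the first concern. Peaks near gene ends were no more common than at random, with 5.43% against 5.74% in WT and 4.11% against 5.67% in KO. A called peak alone therefore does not show that a gene carries the mark. Of the 130 genes in the 5 lipid lists, 15 had a WT peak within 2 kb of a gene end and 8 had a KO peak. None had both. The WT-marked genes included Mlxipl, which encodes the carbohydrate-responsive lipogenic factor ChREBP (5 fragments, 3.01-fold), the lipases Lipe (6 fragments, 2.86-fold) and Pnpla3 (4 fragments, 2.88-fold), and the beta-oxidation genes Decr1 (9 fragments, 5.80-fold) and Acaa2 (6 fragments, 4.06-fold). By caller p, the Pnpla3, Lipe and Mlxipl peaks ranked only 54359, 49289 and 32635 of the 54397 WT peaks. Acaa2 ranked 13444 and Decr1 376. The caller −log10 q was 0.37 for Pnpla3 and Lipe and 0.48 for Mlxipl, against 1.07 for Acaa2 and 3.01 for Decr1. The KO-marked genes included Acsl5 (5 fragments, 3.83-fold), Eci2 (5 fragments, 3.83-fold) and Cyp4a10 (5 fragments, 3.83-fold). Their peaks ranked 16574, 14441 and 18864 of the 41907 KO peaks. Cholesterol synthesis was divided evenly. Stard4, Fdps, Cyp51 and Hmgcs1 were marked in WT only, with 4 to 7 fragments, and Lss, Nsdhl and Sc5d were among those marked in KO only. Of these, Lss had the most fragments, 7, and a fold of 5.10. Nsdhl and Sc5d were named after their values were seen.

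With so few marked genes, even a complete lack of shared lipid genes could not stand apart from random lists. All 15 WT-marked lipid genes lacked a KO peak, against a mean of 13.54 in matched random lists (percentile 89.2). All 8 KO-marked genes lacked a WT peak, against a mean of 6.46 (percentile 90.9). With the gene body and 2 kb on both sides, cholesterol synthesis stood apart in retention and gain, with fewer shared genes than random lists, the setting for gain being chosen after seeing the data. The numbers marked near gene ends were within the random range, at percentile 20.1 in WT and 25.6 in KO.

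Genes that define the hepatocyte stood apart in KO. Of 36 hepatocyte identity genes, 8 had a KO peak near an end, against a mean of 2.81 in random lists (percentile 99.7), and 3 had a WT peak (percentile 16.2). Chance would place 0.306 of the 23 lists outside in KO, where 2 were, and 14.06% of random sets of 46 lists, for both genotypes together, held a list as extreme as this one. The KO genes included Cyp3a11 (7 fragments, 5.10-fold), Tdo2 (6 fragments, 4.46-fold), Alb, Cyp2e1, Hnf4a, Serpina3k and Tat, the last 5 named after their values were seen. The WT genes were the transcription factors Cebpa (7 fragments, 3.75-fold), Nr5a2 (5 fragments, 3.48-fold) and Foxa3 (4 fragments, 2.89-fold). By caller p, these peaks ranked 15894, 28326 and 54317 of the 54397 WT peaks. Genes of bile acid synthesis and transport also stood apart in KO, with 5 of 19 marked against a mean of 1.49 (percentile 99.3). In WT 5 of 19 were marked as well, at percentile 92.0. Cyp27a1 was marked in both, with 7 fragments in WT and 6 in KO, by peaks that did not overlap. The bile acid receptor gene Nr1h4 and the uptake transporter gene Slc10a1 were marked in KO only, each with 6 fragments and a fold of 4.46. Abcc2, Abcb4, Akr1d1 and Cyp8b1 were marked in WT only. The following settings were chosen after seeing the data. With a 1 kb window, 1 hepatocyte identity gene and 0 bile acid genes were marked in KO, at percentiles 43.3 and 24.3. With the strongest 5000 peaks of each list, 1 gene of each was marked, at percentiles 81.7 and 89.7. With the gene body and 2 kb on both sides, hepatocyte identity was at percentile 88.4 and bile acid genes at 99.9.

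The other lists did not stand apart in coverage in either genotype. In KO the random range began at 0 for every list, so none could have stood apart by having too few marked genes. The same held for some lists in WT. Lipoprotein and sterol export genes had 6 of 25 members marked in WT, among them Mttp and Abca1, and 0 in KO (percentiles 90.9 and 6.4). Stellate cell and fibrosis markers had 5 of 20 marked in WT, with Dcn the strongest at 7 fragments, and 0 in KO (percentiles 90.2 and 10.2). Kupffer cell and macrophage markers had 4 of 20 in WT and 1 in KO, sinusoidal endothelial markers 4 of 20 and 1, lymphocyte markers 5 of 21 and 2, and cholangiocyte markers 2 of 17 and 1. These were at percentiles 42.5 to 88.2 in WT and 36.3 to 64.1 in KO. Over all protein-coding genes, 14.1% were marked in WT and 7.8% in KO, so lower KO numbers are not particular to these lists. Glucose and glycogen genes had 0 of 22 in WT and 2 in KO, among them Slc2a2. The WT number was at percentile 1.8 but could not have stood apart, since its random range began at 0. Of 27 inflammation genes, Tlr4 was marked in WT. Genes of the unfolded protein and integrated stress response had 6 of 26 in WT and 4 in KO, with the sensor genes Atf6 and Eif2ak3 marked in both. The strongest peaks of Atf6 and Eif2ak3 did not overlap between the genotypes. The comparison lists gave 6 of 24 ubiquitously expressed genes in WT and 1 in KO (percentiles 92.1 and 29.5). Genes of other tissues had 3 of 36 in WT and 2 in KO (percentiles 16.7 and 34.9).

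Genes close to the propionylation and proteasome pathways were marked in both directions. Of 23 genes for propionyl-CoA supply and removal, 3 were marked in WT and 3 in KO. Aldh6a1, which makes propionyl-CoA from valine breakdown, was in both, with 6 and 5 fragments at different ends of the gene. Of 24 histone acyltransferase and deacylase genes, 4 were marked in WT, including Kat7 with 7 fragments and a fold of 4.70, and 3 in KO. Sirt3 and its neighbour Psmd13 shared their peaks, 1 in WT and 1 in KO with 8 fragments each, which did not overlap one another. Of 34 proteasome subunit genes 6 were marked in WT and 2 in KO (percentiles 72.8 and 37.1). Of 19 m6A genes 5 were marked in WT (percentile 91.8) and 4 in KO (96.3), the latter including the reader Ythdc1 (7 fragments, 5.10-fold). In retention, 1 of 23 lists stood apart. Of the 3 cell cycle genes marked in WT, 1 (Pcna) lacked a KO peak, against a mean of 2.73 (percentile 1.1), and Cdkn1a and Mcm3 had peaks in both. The strongest peaks of Cdkn1a and Mcm3, with 4 to 6 fragments, lay at opposite gene ends in WT and KO and did not overlap. By the random lists themselves, chance would place 0.167 of 23 lists outside. In gain, 0 lists stood apart, and lists with 1 or 2 marked genes could not have done so in either direction, since their random range began at 0. In both comparisons the random range reached the full number of marked genes for every list, so a complete loss or gain could not have stood apart. Cell cycle genes no longer stood apart in 6 of the 7 other settings that gave a value.

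**Figure D2:**
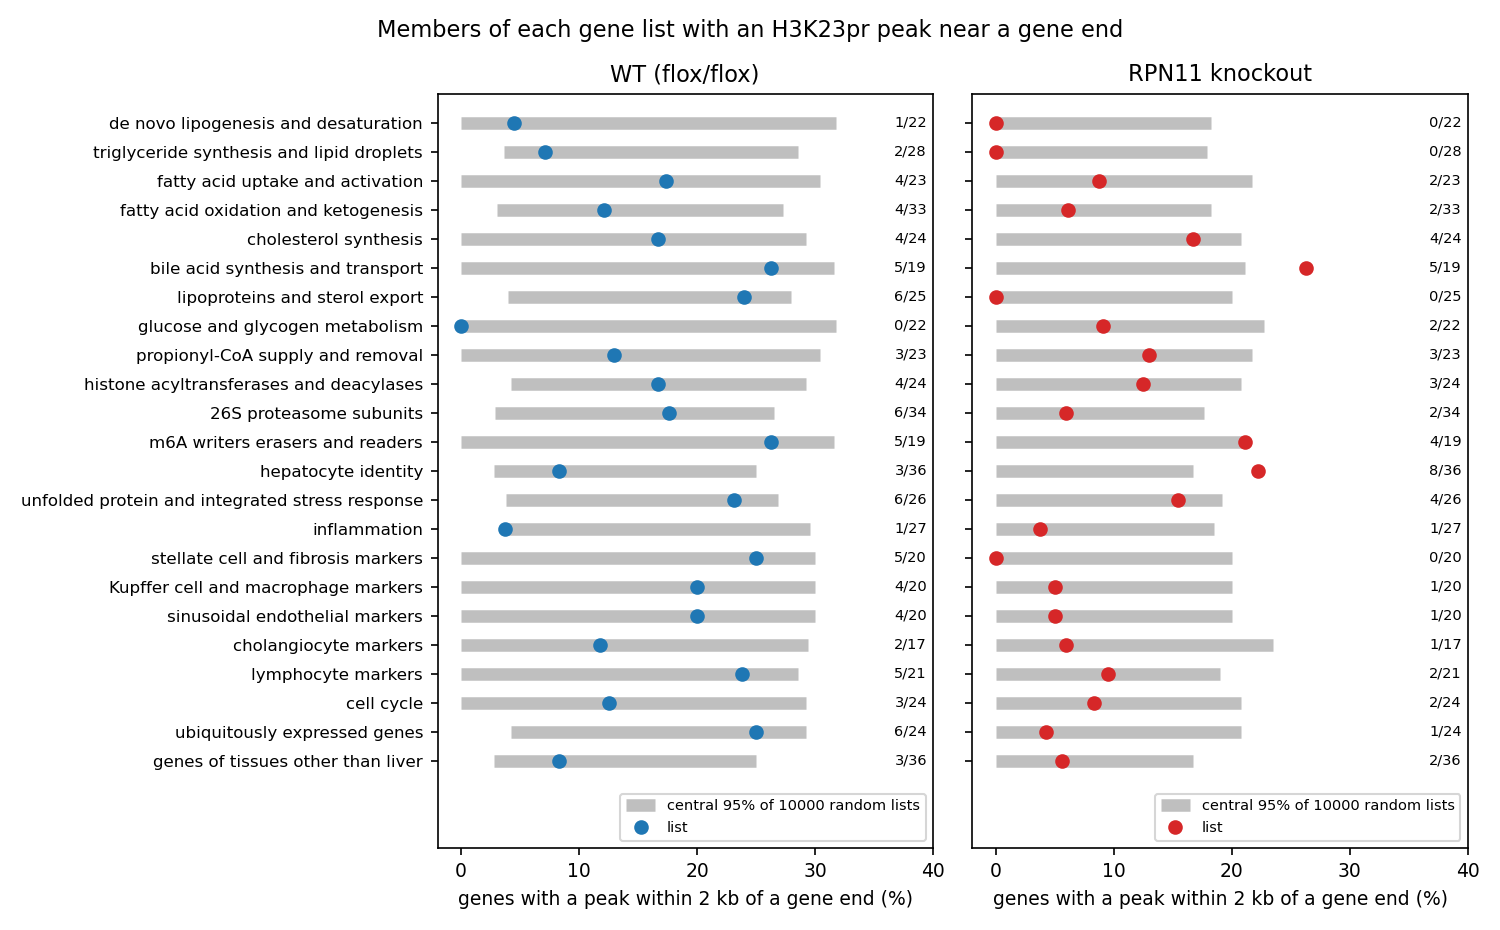
Share of each gene list with a peak within 2 kb of a gene end (x axis, percent) in WT (left, blue) and KO (right, red), with the central 95% of 10000 random lists as grey bars and the numbers of marked and all members at the right. Hepatocyte identity (8 of 36) and bile acid genes (5 of 19) lie beyond the bars in KO, and no list does in WT.

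Over all 21887 protein-coding genes, 2770 were marked in WT only, 1385 in KO only and 317 in both. Independent lists of these sizes would share 240.1 genes. KO peaks moved by 20 to 100 kb shared a mean of 381.96 (339 to 421) but also marked more genes, 2193.59 against 1702. As a share of KO-marked genes this was 17.4%, against 18.6% observed. In 19 of the 317 shared genes a WT peak near the ends overlapped a KO peak. The strongest WT-only genes were Rbp7, a retinol-binding protein gene (chromosome 4, 149448830 to 149448965, 11 fragments, 6.96-fold), and the mitochondrial genes Dnajc19 and Ndufa10 (10 fragments and 6.50-fold each). Pramel32 and Traf1 had the same values. Among KO-only genes, Brox had the lowest caller p (chromosome 1, 183299202 to 183299367, 40 fragments, 4.31-fold). Vmn2r129 followed with 11 fragments, and Ehbp1, Ly6f, Mmp1b, Olfr1249 and Pnp had 9 fragments and a fold of 6.38 each. Of the genes marked in both, Wls, which encodes a Wnt secretion factor, ranked first. Its site on chromosome 3 (159939466 to 159939661 in WT) held 275 fragments in WT and 192 in KO, at folds of 3.58 and 3.36. This site lay outside the gene and was the last WT peak on the chromosome, with a background of 76.2 fragments in WT and 56.5 in KO. The major urinary protein genes Mup22 and Mup11 were also in this group, with 6 to 9 fragments. WT-only genes outnumbered KO-only genes 2.00 times as called, but at a caller q of 0.05 or smaller they were 418 and 490.

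Of the WT peaks with 31 or more fragments, 32 of 50 overlapped a KO peak, and of the KO peaks 30 of 58 overlapped a WT peak. The WT peaks with the most fragments were outside this group, such as 12571 fragments on chromosome 2 (98666750 to 98667194) and 3551 on chromosome 9 (3024415 to 3024537), with no overlapping KO peak. Their folds were 1.502 and 2.890 over backgrounds of 8367.5 and 1228 fragments, against a genome-wide WT background of 0.692. There were 56 overlapping pairs with more than 10 fragments in both lists, and 16 of them touched a protein-coding gene. In 14 of them, including the strongest pair below, the WT peak was the last on its chromosome. The strongest pair was outside genes on chromosome 14 (124801601 to 124802196 in WT), with 904 fragments in WT and 685 in KO. Scaled to the library, KO had 0.667 times the WT fragments there (95% interval 0.603 to 0.737). Over the 56 pairs the median KO to WT ratio of IP fragments, scaled to library size, was 0.771 and the median ratio of fold was 1.58. Scaling was by fragment number only, while mean IP fragment size was 97 bp in WT and 71 bp in KO. Scaled ratios under 1 therefore cannot be told apart from the shorter KO fragments. Background exceeded the genome-wide level more than 2 times in WT in 55 of these pairs and in KO in 43, where a peak can belong to more than 1 pair, and the median WT to KO background ratio was 2.06.

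Among genes at these sites, 3 were picked after their values were seen, for a fold that differed far more than the IP signal. D5Ertd579e (chromosome 5, 36630423 to 36630749 in WT) had 76 IP fragments in both genotypes. Its fold was 49.1 in KO and 4.18 in WT, where the background was 0.568 and 17.4 fragments. Vps45, a vesicle sorting gene, had 63 fragments in KO and 82 in WT, a ratio scaled to library size of 0.676 (95% interval 0.479 to 0.951), at folds of 13.2 and 3.06. Mogat1, an acylglycerol transferase gene of triglyceride synthesis, had an internal site on chromosome 1 (78573812 to 78573965 in WT, with a further WT peak under the same KO peak) with 26 fragments in KO and 30 in WT. The KO to WT ratio scaled to library size there was 0.763 (95% interval 0.433 to 1.33), and 1.91 (0.929 to 4.15) against the further WT peak of 12 fragments. The folds were 14.8 in KO and 2.97 and 2.43 in WT. The scaled ratios of Vps45 and Mogat1 were not corrected for the shorter KO fragments either. Across all 468 overlapping pairs the Spearman correlation was 0.09 for fold and 0.49 for summit fragments. These correlations are across peaks, which are not independent replicates.

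**Figure D3:**
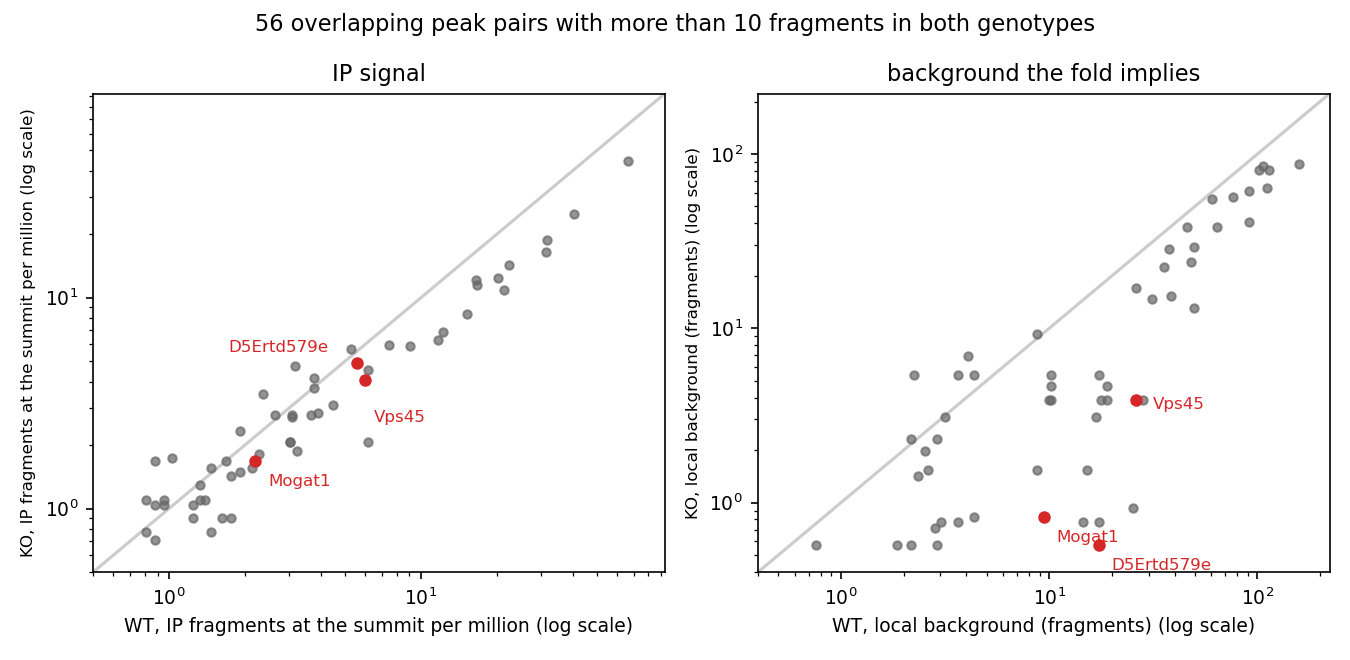
The 56 overlapping pairs with more than 10 fragments in both lists, with WT on the x axis and KO on the y axis (log scales), as IP fragments at the summit scaled to library size (left) and as background in fragments (right). The grey line marks equal values; D5Ertd579e, Vps45 and Mogat1 (red) lie closer to it for IP signal than for background.

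In the full lists, WT had 54397 peaks covering 7.88 Mb and KO had 41907 covering 4.31 Mb. KO thus had 0.770 times the peaks and 0.547 times the length, with a median width of 92 bp against 130 bp. The narrowest peak equalled the mean IP fragment size in each list, 97 bp in WT and 71 bp in KO. Width and covered length therefore cannot be told apart from fragment size. The median peak had 5 fragments in both. The caller's median fold was 3.52 in WT and 3.83 in KO. The order turned with the threshold. At a caller q of 0.05 or smaller there were 5186 WT and 11416 KO peaks, at a caller −log10 p of 10 or more 67 and 152, and above 10 fragments 166 and 222. It turned back among the highest peaks, with 38 and 34 at 51 or more fragments and 29 and 14 above 100.

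Almost all peaks were found in 1 genotype only. Of the WT peaks, 464 overlapped a KO peak, 0.853% (95% interval 0.777 to 0.934), and of the KO peaks 462, 1.102% (1.00 to 1.21). Random placement gave 0.422% and 0.551%, and local moves gave 0.504% and 0.639%. The share was 0.617% for WT peaks of 4 fragments, 77.3% for those of 16 to 30 and 64.0% (49.2 to 77.1) for the 50 WT peaks of 31 or more. All of these 50 had a background over 2 times the lowest in the list, and local moves gave 11% for them. At the genome-wide background the share was 1.397% for WT peaks of 8 or more fragments. By location, 5.43% of WT peaks (5.25 to 5.63) and 4.11% of KO peaks (3.92 to 4.30) lay within 2 kb of a gene end, against 5.74% and 5.67% at random. Peaks inside genes made up 40.8% in WT and 41.8% in KO, against 37.4% and 37.3% at random.

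**Figure D4:**
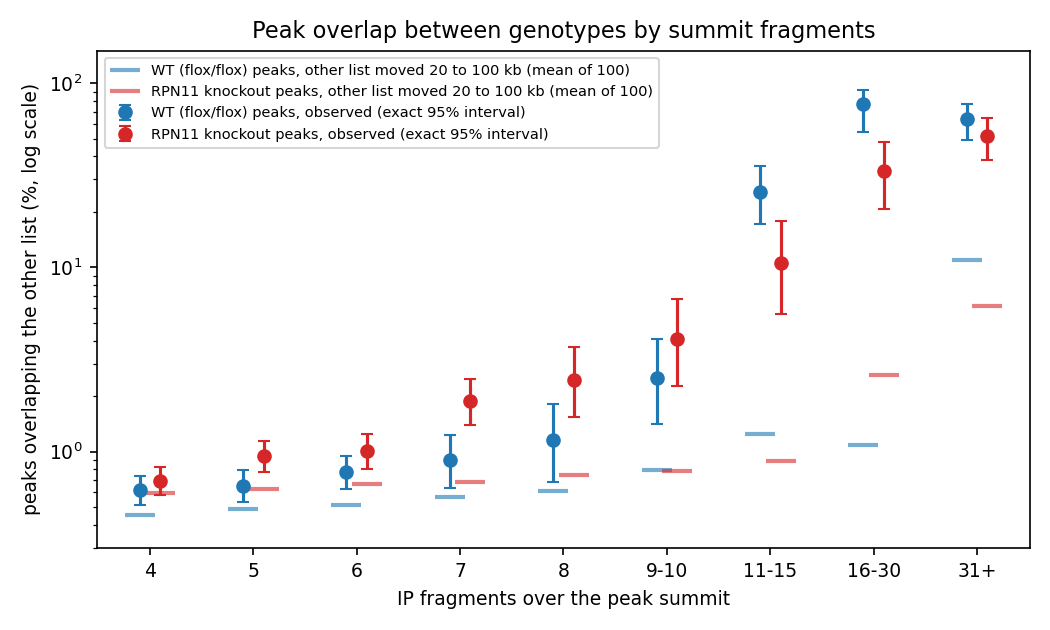
Share of peaks that overlap the other genotype's list (y axis, percent, log scale) by IP fragments at the summit (x axis), with WT in blue, KO in red, exact 95% intervals as bars and the mean of 100 local moves of the other list as dashes. The share rises from 0.617% of WT peaks with 4 fragments to 77.3% of those with 16 to 30. It is 64.0% of those with 31 or more, all of which had raised background.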

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

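Alternatives at a caller q of 0.05, above 10 fragments, at the genome-wide background and at 5 or more fragments, those by summit fragments, and all those of gain and coverage were chosen after seeing the data. Of 125 alternative values 47 stayed on their side of the threshold, inside their interval or, for counts and ratios, within 1.5 times; the others follow, and the cause was not tested. KO over WT peak number and covered length turned to 2.27 and 2.70 at a −log10 p of 10, 2.20 and 1.52 at q 0.05, and 1.34 and 1.52 above 10 fragments; at the genome-wide background they were 0.982 and 0.693, so the lower KO peak number nearly vanished. Overlap in WT and KO became 0.579% and 0.701% at or above the WT median fold, 38.8% and 17.1% at −log10 p 10, 1.24% in both with the strongest 5000, 1.35% and 0.613% at q 0.05, 0.561% and 0.572% at the genome-wide background, 0.370% and 0.480% with 50% of each peak, and 4.93% and 6.57% within 1000 bp; with equal numbers KO became 0.921%. Genes marked in WT only, KO only and both were 1678, 882 and 111 at the median fold, 1, 4 and 2 at −log10 p 10, 402, 227 and 4 with the strongest 5000, 418, 490 and 17 at q 0.05, 1548, 731 and 78 within 1 kb, and 5103, 2375 and 1480 within 5 kb. With the gene body, 4389 were WT only and 4721 in both. WT-only over KO-only genes turned to 0.25 at −log10 p 10 and 0.853 at q 0.05. Peaks near gene ends were 5.76% in WT at the median fold, 5.97% and 4.61% in WT and KO at −log10 p 10, and 2.70% and 1.81% within 1 kb. Lists apart in retention were 0 at the median fold, at −log10 p 10, with the strongest 5000, within 1 kb, with unmatched random lists and when a KO peak in the body or 5 kb flanks counted as kept, and 2 with the gene body (cholesterol synthesis high, bile acid genes low); within 5 kb it was 1, but the proteasome list and not cell cycle. The cell cycle percentile was 54.7 at the median fold, 56 within 1 kb, 5.8 within 5 kb, 13.5 with the gene body, 1.6 unmatched and 20.2 with the wider kept rule. With the gene body, 57.1% of WT-marked lipid genes lacked KO marking, and 1 list, cholesterol synthesis, stood apart in gain. Lists apart in WT coverage were 1 within 5 kb, 2 with the gene body and 1 with the strongest 5000; in KO coverage 0 within 1 kb, 4 with the gene body and 0 with the strongest 5000. In KO, hepatocyte identity and bile acid genes were at percentiles 43.3 and 24.3 within 1 kb and 81.7 and 89.7 with the strongest 5000, and hepatocyte identity at 88.4 with the gene body. At 5 or more fragments Psmd14 in WT was at 92.0 and Acss3 in KO at 91.8. The correlation of overlapping pairs was 0.25 by fragments per kb and 0.49 by summit fragments. At −log10 p 10 no lipid or cell cycle gene was marked, and with the strongest 5000 no cell cycle gene was, so no value could be given. Most peaks had 4 to 6 fragments, which limits what either list can show. No paired analysis was possible because each genotype had 1 IP library.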

Other observations

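Of the tests in this part, those on chance positions, on IP fragments as the whole cause and on the most extreme list by chance were chosen after their results or the values behind them had been seen. So were the split of the background test into its 2 changes and the allowance for 46 lists, which turned 2 verdicts into open ones. The 3 patterns were themselves picked from the results. The higher KO fold at strong shared sites had been weighed first and was then set aside for the liver genes, and its values stand in the report.

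The gene windows of 5 kb, chosen after seeing the data, show the liver genes at greater reach. Within 5 kb of a gene end, 17 of 36 hepatocyte identity genes had a KO peak, against a random mean of 6.38, and 12 had a WT peak, against 10.84. For bile acid genes the numbers were 9 of 19 in KO (random mean 3.36) and 10 of 19 in WT (5.71, percentile 97.7). Genes of other tissues had 3 of 36 in KO (percentile 6.7) and ubiquitously expressed genes 3 of 24 (percentile 27.9).

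For the low overlap between the genotypes, chance positions as the only source of overlap among weak peaks stay open. WT peaks of 4 to 6 fragments overlapped KO peaks 1.28 times as often (95% interval 1.15 to 1.43) as KO peaks moved by 500 bp to 2 kb. By its rule this counted against chance positions. The test cannot decide it, because moved peaks could fall where no peak can be called, which lowers the expected overlap. Weakly marked sites common to both livers, each found in 1 library only at this depth, stay open: 1.397% (0.724 to 2.43) of WT peaks at the genome-wide background with 8 or more fragments overlapped, against 0.629% (0.511 to 0.766) of those with 4. The rule written before this test would have counted overlapping intervals against the explanation, but it was loosened after the value was seen: overlapping intervals do not exclude a difference, and the lower limit 0.724 lies above 0.629. The value does not settle it either, since 12 peaks stand behind the first share and chance overlap of all WT peaks also grew, from 0.451% at 4 fragments to 0.610% at 8. A difference by genotype stays open and was not tested.

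KO had fewer peaks than WT in all but more at low q; scored again with the WT genome-wide background as a minimum and held to the WT threshold, 3626 KO peaks remained, against 5186 in WT and 11416 by the KO list's own q. Whether a lower genome-wide background in KO, whose fragments were shorter, accounts for the turn stays open, since this changed background and threshold together. The background alone left 11416 KO peaks and the threshold alone 10882. With the same threshold for both lists, WT had more at the KO threshold (13424 against 11416) and KO more at the WT threshold (10882 against 5186). At the genome-wide background a peak of 6 fragments had a −log10 p of 5.08 in WT and 5.64 in KO. The thresholds at q 0.05 were 5.34 and 4.97, so such peaks passed in KO only. More IP fragments over KO peaks as the whole cause were argued against for raw fragment numbers only. KO had 0.621 times the WT peaks at 7 or more fragments (0.597 to 0.647), the lowest ratio among minima of 4 to 31. A higher KO signal after correction for library and fragment size stays open, since these numbers were not corrected for either. The ratio was 0.672 at 6 or more, 0.981 at 10 or more and 1.51 at 16 or more. At 11 or more it was 1.34, where KO had 56 more peaks, against 6230 more at low q. An effect of genotype on the background itself was not tested.

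Liver genes stood apart in KO by peaks near their ends. A few peaks each counted for several genes of a cluster were argued against, since the 8 marked hepatocyte identity genes had 8 different peaks. Dense KO peaks in the surrounding regions stay open: against lists matched on KO peaks 5 to 200 kb away the 8 genes were at percentile 98.6 (mean 3.62, range 1 to 7), but this list was picked as the most extreme of 46, and 2.21% of the matched lists were as high. Chance stays open too, because 14.06% of random sets of 46 lists held a list at least as extreme. A difference by genotype likewise stays open and was not tested.

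The number of KO peaks over WT peaks ran from 0.638 on chromosome 11 to 0.856 on chromosome 3 and had a Pearson correlation of −0.71 with gene density over 19 autosomes. Chromosome X held 5.19 peaks per Mb in WT and 4.06 in KO, against 21.7 and 16.7 on autosomes. The ratio of X to autosomes was 0.239 in WT and 0.243 in KO. The mice were male, so the copy number of X and the mark cannot be told apart here.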
